A study of Mus musculus with 8 samples.

How the data were processed

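RNA sequencing of mouse embryonic stem cells was taken from 8 libraries in 4 groups: Control and HSVTK cells, each with DMSO or ganciclovir (GANC), with 2 libraries per group. Samples were grouped by cell group and treatment as the labels give them. Per the labels, RNA was extracted with phenol and chloroform and libraries were made with a VAHTS Universal V6 kit. The submitters' processing notes name fastp 0.23.2, HISAT2 2.1.0, featureCounts 2.0.1, DESeq2 1.40.2 and the build GRCm39, without roles, order or parameters. Strand, the treatment of reads with several matches and the annotation release are not given in the sources used here.

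The authors deposited a table of raw counts per gene, whole numbers without normalization, for 57010 Ensembl genes, of which 1606 have no symbol. The authors also deposited a table of FPKM, made before deposit from the same counts by dividing by gene length and by the counts assigned to genes in that library. This was checked here: all 456080 FPKM values equal that quotient within 1e-05. Libraries held 29704460 to 34184475 counts and 23777 to 25656 genes with a count. The 10 most abundant genes took 6.45 to 6.85% of the counts and mitochondrial genes 2.88 to 3.56%. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 3.86 in Control DMSO, 8.39 in Control GANC, 3.58 in HSVTK DMSO and 6.24 in HSVTK GANC, over genes with at least 20 counts in both libraries together.

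The main test, fixed with the gene lists, the rule for named genes and all but 1 of the other settings before the data were examined, was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. It used the deposited counts, TMM scaling, the default filter of filterByExpr by group and all 8 libraries in a fit with a mean per group, which leaves 4 residual degrees of freedom. The filter kept 17976 genes. The biological coefficient of variation was 6.31%. Adjusted p is the Benjamini-Hochberg value over all tested genes, and a gene was called below 0.05. There were 5 comparisons: GANC against DMSO in HSVTK cells, the same in Control cells, the difference of both responses, and HSVTK against Control cells under DMSO and under GANC. Fold changes are on the log2 scale with a standard error, taken as the fold change divided by the square root of the F statistic. Where a group has few counts, this value understates the error. Levels are in CPM, counts scaled to a library of 1e+06 counts with TMM factors, as mean ± SD of 2 libraries. Where a group had 0 counts, a floor of 3 counts over the group gave a bound, and where it had a few, an exact 95% counting interval is given.

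For gene groups, 28 lists with 748 genes were written from general knowledge, of which 739 genes have a symbol in the files. They include markers of primitive endoderm, mesoderm, neuroectoderm, trophectoderm and fibroblasts as other cell types. Members were matched by symbol, which can stand for more than 1 Ensembl gene. The glycolysis and hypoxia list of 30 symbols thus has 31 tested members. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison. The same test grouped all tested genes by chromosome, while chromosome medians are over genes with a mean CPM of at least 1 unless stated. Chromosome and gene order came from the GENCODE vM21 annotation, matched by Ensembl ID for 17556 of the tested genes (97.7%). That annotation belongs to GRCm38 and not to the build in the submitters' notes, so no coordinates are printed.

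Named genes followed a rule. In each comparison it took the 8 largest positive and 8 largest negative fold changes among called genes with a mean CPM of at least 1 whose libraries did not overlap between the groups, without the last condition for the difference of responses. It also took up to 4 members with the lowest adjusted p from each list that passed its test or had at least 3 called members. Always eligible were Zscan4c, Zscan4d, Zscan4f, Duxf3, Zfp352, Pou5f1, Nanog, Sox2, Trp53, Cdkn1a, Mdm2 and Tk1. Symbols that are only a model number, clone or Ensembl ID were passed over among the largest changes: 1 higher and 2 lower for GANC in HSVTK cells, 1 and 5 in Control cells, 3 and 0 for the difference of responses, 0 and 3 for the cell groups under DMSO and 4 and 4 under GANC. Not every eligible list member is named, and some are not reported here.

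After the chromosome test was seen, a running median of the fold change over 31 neighbouring genes with a mean CPM of at least 5 was computed. A segment was called where it lay beyond 0.35 from 0 for at least 10 windows, and 1000 shuffles of the gene order gave the chance level. The pipeline was tested on simulated data with 200 changed genes in each of 3 simulations of 17976 genes. The changed genes were drawn from those with a mean CPM of at least 1, so recovery of weaker genes was not measured. edgeR recovered 71.1% of genes changed 1.5-fold, 88.6% of those changed 2-fold and 97.0% of those changed 4-fold, and 3.57% of its calls were unchanged genes. Fewer genes were changed than were called in any comparison of the data, so the dependence on scaling was not probed.

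The other settings were DESeq2 1.42.0, RLE or library size scaling, no filter or a CPM of 1 in 2 samples, the replicate number as a block, only the 4 libraries compared, a test against a 1.5-fold change, limma on log2 of the FPKM plus 1 or plus 0.1, an estimated correlation for camera, the fry test, and leaving out each library. Counts without the genes of the called segments were added after seeing the data. All columns of per-sample values were used. The level of the HSVTK transgene was not analysed here.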

Results

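RNA sequencing profiled mouse embryonic stem cells in 4 groups of 2 libraries. These are cultured cells of the early embryo that can form all of its tissues. At any time a small share of them passes through a state resembling the 2-cell embryo (the 2C-like state), marked by genes such as Zscan4c and Zfp352. In the HSVTK cells a reporter makes 2C-like cells produce the thymidine kinase of herpes simplex virus, which turns the nucleoside analogue ganciclovir (GANC) into a toxic product, so that the drug is meant to remove those cells. The group labelled Control and the group labelled HSVTK each received GANC or the solvent DMSO. The labels give neither dose nor duration, and they do not say what the Control cells carry. Each library held 29704460 to 34184475 counts assigned to genes, and 17976 genes passed the filter on low counts. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Principal components were taken over the tested genes with the largest variance only. The first, with 35.2% of the variance of those genes, set the HSVTK libraries apart from the Control libraries. The next component, with 22.9%, placed the HSVTK DMSO and HSVTK GANC libraries at opposite ends.

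The 2C-state genes, which the drug is meant to deplete in HSVTK cells, were higher in the libraries labelled HSVTK GANC than in any other group. Zscan4c (ENSMUSG00000054272), a gene of the 2-cell embryo tied to telomere lengthening, stood at 8.70 ± 0.247 CPM (SD, n = 2) in HSVTK GANC. It stood at 4.15 ± 0.786 CPM in HSVTK DMSO, 4.67 ± 0.799 in Control DMSO and 4.57 ± 0.602 in Control GANC. Its log2 fold change between HSVTK GANC and HSVTK DMSO was 1.07 ± 0.18 (SE, adjusted p = 4.28e-05). Zscan4d (ENSMUSG00000090714) rose by 0.75 ± 0.16 on the log2 scale (adjusted p = 0.000638), Zscan4a by 1.07, Zscan4e by 1.22 and the eIF1A-like Gm21761 by 1.27 ± 0.13. Zscan4f (ENSMUSG00000070828) rose by 0.69 ± 0.20 (adjusted p = 0.0105), a call lost without HSVTK DMSO replicate 2 (adjusted p = 0.132) or HSVTK GANC replicate 2 (adjusted p = 0.0702). For Zfp352 (ENSMUSG00000070902) the value was 1.57 ± 0.70 (adjusted p = 0.0985), from 8 to 26 counts per HSVTK library. Duxf3, the transcription factor that turns on the 2C programme, had 0 to 4 counts per library and was not tested. Of the 28 tested members of the 2C list, 17 were higher and 1 lower over all genes, and 23 higher and 1 lower adjusted over the list alone. Their median log2 fold change was 1.07, and limma's camera test gave an adjusted p of 1.26e-08 for the list (adjusted p = 0.0458 with an estimated correlation). In Control cells the same comparison gave 0 higher and 0 lower, over all genes and adjusted over the list alone, with a median of -0.28 (adjusted p = 0.173). The libraries labelled HSVTK GANC also stood apart in their mitochondrial share of counts (3.56 and 3.45%, others at most 3.17%) and in genes with a count (25146 and 25656, others at most 24772). Many of these genes are near-identical copies, and how the deposited counts treated reads that match several copies is not given in the sources used here, so values of single copies are uncertain. Because these genes moved against what the labels imply, the groups are named below as the libraries labelled HSVTK GANC and HSVTK DMSO, and every direction between them, and between either of them and a Control group, rests on those labels.

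**Figure D1:**
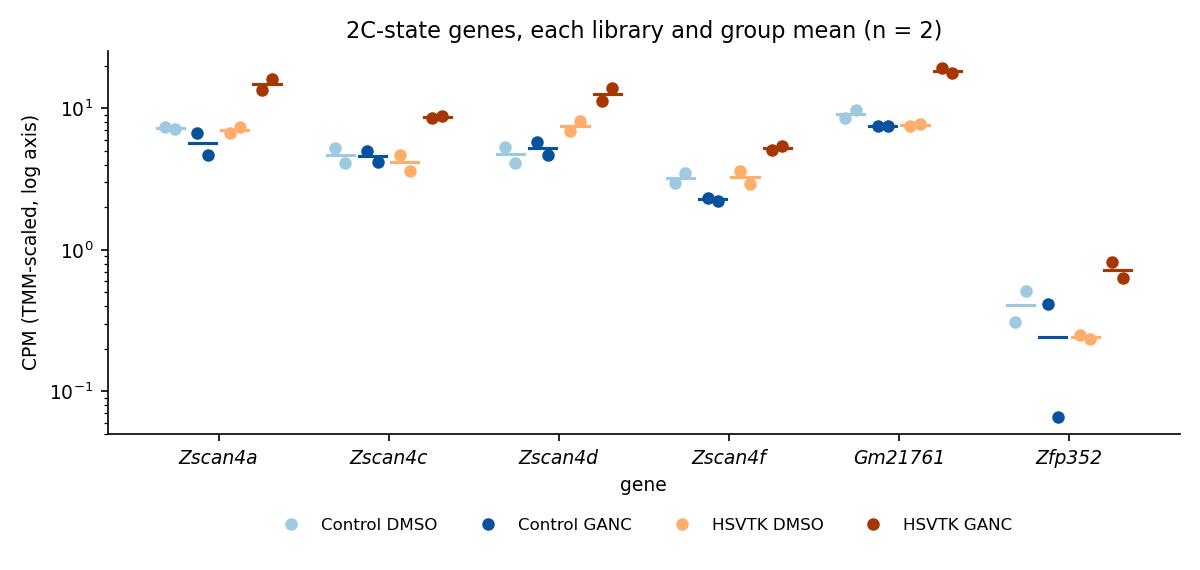
Expression of 6 genes of the 2C list in CPM (library-scaled counts) on a log axis, with 1 point per library and a line at each group mean (n = 2). Zscan4c lies at 8.70 CPM in the libraries labelled HSVTK GANC and between 4.15 and 4.67 CPM in the other groups, while Zfp352 lies below 1 CPM everywhere.

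The first comparison asked what ganciclovir changed in HSVTK cells. Genes of glycolysis and hypoxia and of cholesterol synthesis were lower in the libraries labelled HSVTK GANC than in those labelled HSVTK DMSO, while p53 targets were higher. The largest drops among named genes were in Ndufa4l2, a mitochondrial protein induced by low oxygen, at -3.77 ± 0.19 on the log2 scale (28.6 ± 0.679 to 2.07 ± 1.13 CPM, adjusted p = 9.57e-15), and in the protease inhibitor A2m at -3.16 ± 0.17. Next came the potassium channel subunit Kcng1 at -2.96, the meiotic kinase Aurkc at -2.81, the coatomer subunit Copz2 at -2.70, the oxygen sensor Egln3 at -2.70, the regulator of meiotic entry Stra8 at -2.59 and the synuclein Sncb at -2.59. The largest rises among them were in the heart transcription factor Tbx20 at 3.20 ± 0.42 (adjusted p = 1.35e-06), the integrin Itga8 at 2.76, the hyaluronan-degrading Cemip at 2.37, the sodium-glucose transporter Slc5a1 at 2.27, Trpm1 at 2.23, Apol6 at 2.22, Ano3 at 2.16 and Ms4a6d at 2.14. Ano3 lies in the chromosome 2 segment described at the end. In all, edgeR called 5119 of 17976 genes, 2391 higher and 2728 lower, of which 993 changed at least 2-fold. With library size scaling 2758 were higher and 2325 lower, so the balance of both directions depends on the scaling. Without HSVTK DMSO replicate 1 the count was 3375 and without replicate 2 it was 3295. It was 486 in a test against a 1.5-fold change and 2615 with limma on unfiltered log2(FPKM + 1).

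Of 31 tested genes of the glycolysis and hypoxia list, 25 fell and 1 rose (adjusted over the list alone, 25 fell and 2 rose), with a median of -0.62 (adjusted p = 2.4e-13, and adjusted p = 0.0458 with an estimated correlation). Bnip3, a mitophagy receptor induced by low oxygen, fell by 2.37 ± 0.09 on the log2 scale, and the glucose transporters Slc2a1 and Slc2a3 fell by 1.21 ± 0.05 and 1.16 ± 0.05. Of 24 genes of cholesterol synthesis, 20 fell and 0 rose (adjusted over the list alone, 21 fell and 1 rose), with a median of -0.54 (adjusted p = 3.18e-10, and adjusted p = 0.0458 with an estimated correlation). Insig1, which holds back sterol synthesis, fell by 1.18 ± 0.07, and the enzymes Dhcr7 and Cyp51 by 0.90 and 0.84. Of 33 p53 targets, 19 rose and 1 fell (adjusted over the list alone, 20 rose and 1 fell), with a median of 0.32 (adjusted p = 2.22e-05, and adjusted p = 0.0458 with an estimated correlation). Ccng1 rose by 0.92 ± 0.06, the kinase Plk2 by 0.72 and Trp53inp1 by 0.61. The gene that fell was Ddit4, which is also on the glycolysis and hypoxia list, at -0.62 ± 0.07. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose by 0.39 ± 0.09 (adjusted p = 0.00217, and 0.0627 without HSVTK DMSO replicate 1). Trp53 itself rose by 0.19 ± 0.06 (adjusted p = 0.0209), a call lost without HSVTK DMSO replicate 1 (0.114), HSVTK DMSO replicate 2 (0.131) or HSVTK GANC replicate 1 (0.408), and with limma on log2(FPKM + 1) (0.0508). Mdm2, the p53 antagonist, stood at 0.16 ± 0.07 (adjusted p = 0.0741). Its call changed with the setting, and the adjusted p was 0.0314 with library size scaling.

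Genes of formative and primed pluripotency, the states that follow the naive one, split: 4 of 20 rose and 8 fell, the same numbers adjusted over the list alone, with a median of -0.09 (adjusted p = 0.0213, and adjusted p = 0.436 with an estimated correlation). Zic2 and Zic5 fell by 2.23 and 2.18, Lef1, an effector of Wnt signalling, by 2.04 ± 0.12 and Otx2 by 1.65 ± 0.13. Without HSVTK GANC replicate 2 the list had an adjusted p of 0.0636. Of 32 G2/M genes, 17 fell and 0 rose, again the same numbers adjusted over the list alone (median -0.17, adjusted p = 0.000531, and adjusted p = 0.164 with an estimated correlation), among them Pttg1 at -0.95, Ccnb2 at -0.53 and Bub1 at -0.52. Telomere maintenance had 6 of 20 members higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.0253, and adjusted p = 0.226 with an estimated correlation), with the helicase Rtel1 at 0.60 ± 0.07. Its adjusted p was 0.141 without HSVTK DMSO replicate 1 and 0.0546 without HSVTK GANC replicate 2. Replication-dependent histones had 3 of 17 members lower and 0 higher, also adjusted over the list alone (median -0.76, adjusted p = 0.0247, and adjusted p = 0.196 with an estimated correlation), and lost the call without HSVTK DMSO replicate 1 (0.139) or HSVTK GANC replicate 1 (0.088). Among the core pluripotency factors, Sox2 fell by 0.31 ± 0.05 (adjusted p = 6.61e-05). Nanog stood at 0.03 ± 0.05 (adjusted p = 0.769) and Pou5f1 at 0.12 ± 0.06 (adjusted p = 0.108), which became 0.0309 with library size scaling and 0.0383 without Control GANC replicate 1. The cellular thymidine kinase Tk1 stood at -0.05 ± 0.07 (adjusted p = 0.628).

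No other list passed the camera test between the libraries labelled HSVTK GANC and HSVTK DMSO. Naive pluripotency had 2 of 29 genes higher and 9 lower (adjusted p = 0.346). Markers of other cell types were mixed: primitive endoderm had 6 of 20 higher and 4 lower (0.858), mesoderm and primitive streak 5 of 17 higher and 4 lower (0.712), neuroectoderm 1 of 11 higher and 1 lower (0.858), trophectoderm 2 of 16 higher and 3 lower (0.535) and fibroblast and feeder markers 1 of 13 higher and 5 lower (0.333). Among repair genes, homologous recombination and Fanconi anaemia had 6 of 38 higher and 7 lower (0.858), end joining 6 of 19 higher and 2 lower (0.397), and mismatch and excision repair 6 of 35 higher and 2 lower (0.858). Checkpoint and replication stress genes had 4 of 29 higher and 11 lower (0.236), with the kinase Atm at 0.62 ± 0.08 and Dtl at -0.42 ± 0.06. G1/S and replication had 3 of 34 higher and 6 lower (0.658), apoptosis regulators 5 of 26 higher and 6 lower (0.858), and nucleoside metabolism and transport 6 of 25 higher and 0 lower (0.0804). DNA methylation machinery had 3 of 21 higher and 5 lower (0.858), with the methyltransferase Dnmt3a at -0.67 ± 0.07. Repressors of the 2C state had 5 of 32 higher and 4 lower (0.858), with the chromatin assembly subunit Chaf1b at -0.48 ± 0.07. Interferon response had 5 of 21 higher and 6 lower (0.865), imprinted genes 8 of 32 higher and 5 lower (0.397), mitochondrially encoded genes 6 of 13 higher and 1 lower (0.138), and germline genes 4 of 26 higher and 8 lower (0.34). Immediate early and heat shock genes had 3 of 25 higher and 8 lower (0.346), with Egr1 at -1.96 ± 0.09. Adjusted over the list alone, these numbers differed for primitive endoderm (6 and 5), homologous recombination and Fanconi anaemia (7 and 7), DNA methylation (5 and 5), G1/S (3 and 5), germline (4 and 9) and imprinted genes (9 and 5). For the DNA methylation, trophectoderm and immediate early lists the median lay above 0 and the mean and the test direction below it. The mismatch repair and interferon lists had the opposite order. The nucleoside list passed with library size scaling (0.0418) and without HSVTK GANC replicate 1 (0.0494). In limma's fry test, which does not compare members with other genes, 5 more lists passed: immediate early (0.012), checkpoint (0.0121), nucleoside (0.0121), mismatch repair (0.0245) and germline genes (0.0308).

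**Figure D2:**
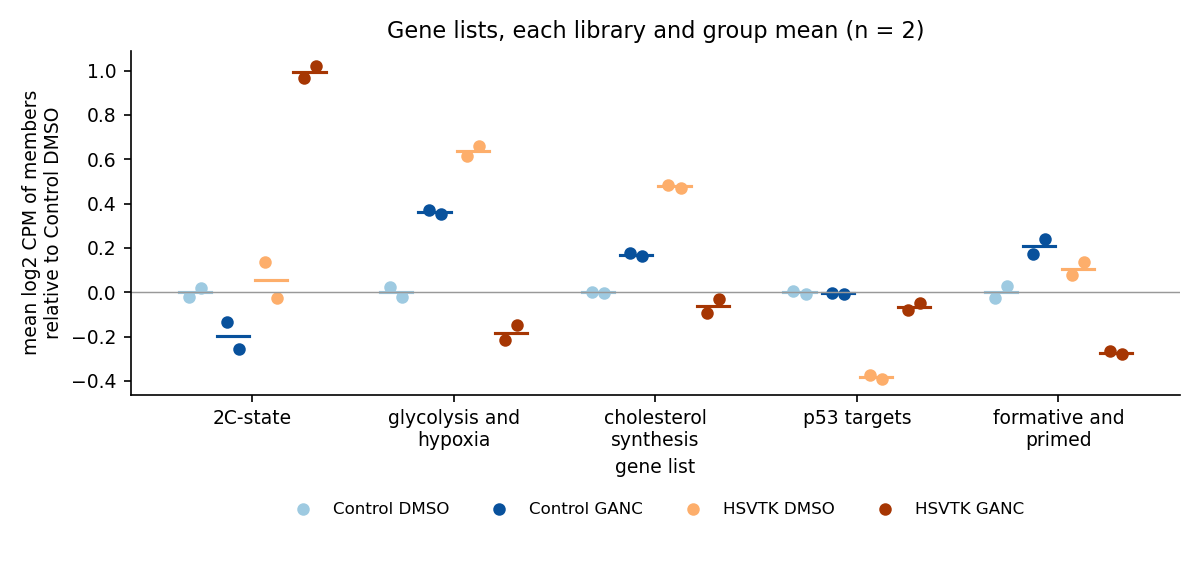
Mean log2 CPM of the members of 5 gene lists, relative to the Control DMSO mean of each member, with 1 point per library and a line at each group mean (n = 2). The 2C list lies at 0.99 in the libraries labelled HSVTK GANC, and the glycolysis and hypoxia list at 0.36 in Control GANC, 0.64 in HSVTK DMSO and -0.18 in HSVTK GANC.

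The second comparison gave the response of Control cells to the drug, the background for the first. Genes of glycolysis and hypoxia were higher in Control GANC than in Control DMSO: 22 of 31 rose and 1 fell (adjusted over the list alone, 25 rose and 1 fell), with a median of 0.26 (adjusted p = 6.91e-12, and adjusted p = 0.225 with an estimated correlation). Bnip3 rose by 1.03 ± 0.09, Egln3 by 1.13 ± 0.10, Ddit4 by 0.74 ± 0.07 and Slc2a1 by 0.55 ± 0.05. Cholesterol synthesis had 8 of 24 members higher and 0 lower (adjusted over the list alone, 10 and 1; median 0.14, adjusted p = 0.000236, and adjusted p = 0.269 with an estimated correlation), with Dhcr7 at 0.61 ± 0.08. Formative and primed genes had 8 of 20 higher and 0 lower (adjusted over the list alone, 10 and 0; median 0.22, adjusted p = 0.000355, and adjusted p = 0.269 with an estimated correlation), with Dnmt3a at 0.38 ± 0.07 and Lef1 at 0.62 ± 0.12. Lef1 missed the threshold with limma on log2(FPKM + 1) (adjusted p = 0.0527). Fibroblast and feeder markers had 4 of 13 higher and 0 lower (adjusted over the list alone, 5 and 0; median 0.41, adjusted p = 0.0202, and adjusted p = 0.269 with an estimated correlation), a call lost without Control DMSO replicate 1 (0.252) or Control GANC replicate 2 (0.107). In this list Fn1, which stem cells also express, rose by 0.41 ± 0.05. The p53 targets had 1 of 33 higher and 6 lower (adjusted over the list alone, 2 and 6; adjusted p = 0.471).

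Among genes with a mean CPM of at least 1, the largest rises in Control cells were in the amine oxidase Aoc3 at 2.33 ± 0.44 (adjusted p = 0.00127), in Tbx3os2 at 2.13, in Ndufa4l2, 4.29-fold (adjusted p = 4.81e-08), in A2m at 1.99 ± 0.21 and in Ppp1r1b at 1.77, followed by Tspan1 at 1.55, the elastase Cela1, 2.83-fold, and Coro2a at 1.45. The largest drops were in the pseudogene Gpi-ps at -2.01 ± 0.48 (adjusted p = 0.00914), Nrip2 at -1.32, the pseudogene Llph-ps2, 2.46-fold lower, Myadml2os at -1.23, Ms4a10 at -1.20, Acat3 at -1.17, Cyp2b23 at -1.14 and Tmem151a at -1.11. Reads of the pseudogenes may belong to their parent genes, and those of the antisense genes Tbx3os2 and Myadml2os to their partners, as strand is not given in the sources used here. Sox2 stood at 0.18 ± 0.05 (adjusted p = 0.0365) and Mdm2 at -0.24 ± 0.07 (adjusted p = 0.0192). Both calls were lost without Control DMSO replicate 1 (0.228 and 0.113), Control DMSO replicate 2 (0.173 and 0.187) or Control GANC replicate 2 (0.0827 and 0.173), and with limma on log2(FPKM + 1) (0.0581 and 0.102). The values of Pou5f1 (0.14), Nanog (-0.01), Trp53 (0.02), Cdkn1a (0.14), Tk1 (0.11), Zscan4c (-0.03), Zscan4d (0.15), Zscan4f (-0.51) and Zfp352 (-0.72) did not pass the test, though Pou5f1 did without Control GANC replicate 1 (0.00934). In all, edgeR called 1453 genes, 850 higher and 603 lower, and 98 of them changed at least 2-fold. Without Control DMSO replicate 1 the count was 596, without Control DMSO replicate 2 it was 431 and without Control GANC replicate 2 it was 735. It was 923 with only these 4 libraries in the fit, 562 with limma on log2(FPKM + 1), 519 with a pseudocount of 0.1, 29 without a filter and 6 in a test against a 1.5-fold change. Of the 88 named genes called here, 64 lost their call in at least 1 alternative setting or left-out library, leaving aside the 1.5-fold test and the unfiltered fit. Aoc3, Ndufa4l2 and A2m kept theirs.

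The difference between both drug responses was tested as an interaction, and 4595 genes passed, 2087 with a higher and 2508 with a lower response in HSVTK than in Control cells. The count was 815 in a test against a 1.5-fold change and 1981 with limma on unfiltered log2(FPKM + 1). Genes called in both drug comparisons mostly moved apart. Of 770 such genes, 654 (84.9%) went in opposite directions, 428 of them lower in HSVTK GANC and higher in Control GANC and 226 the reverse. For independent lists of these sizes 129 and 80.2 would be shared in these directions, against 58 both higher (113 for independent lists) and 58 both lower (91.5). The comparisons share no library. These directions rest on the treatment labels: with those of 1 cell group exchanged, the 654 genes would move the same way and the others apart. Ndufa4l2, A2m and Aoc3 had the most negative differences of response among named genes, at -5.88 ± 0.27, -5.15 ± 0.27 and -4.69 ± 0.58 on the log2 scale, followed by Aurkc at -3.88, Egln3 at -3.83, the glutamate receptor subunit Grin1 at -3.82, the lysyl oxidase Loxl2 at -3.65 and Copz2 at -3.61. The most positive were in Tbx20 at 3.12 ± 0.57, Cemip at 2.97, Ms4a10 at 2.95, the melanocortin receptor Mc5r at 2.94, Nkx2-9 at 2.93, Itga8 at 2.82, Pkd1l2 at 2.79 and Vmn2r79 at 2.77. Zscan4c differed by 1.10 ± 0.26 (adjusted p = 0.00208), Zscan4f by 1.20 ± 0.30 (0.0035), Sox2 by -0.50 ± 0.08 (1.83e-05) and Mdm2 by 0.40 ± 0.09 (0.00175).

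By list, the responses differed for 2C-state genes, with 14 of 28 higher and 1 lower (adjusted over the list alone, 18 and 1; median 1.31, adjusted p = 6.02e-07, and adjusted p = 0.0495 with an estimated correlation). Glycolysis and hypoxia had 26 of 31 lower and 1 higher, the same numbers adjusted over the list alone (median -0.83, adjusted p = 5.45e-15, and adjusted p = 0.0495 with an estimated correlation). Cholesterol synthesis had 20 of 24 lower and 1 higher (adjusted over the list alone, 21 and 1; median -0.73, adjusted p = 7.21e-11, and adjusted p = 0.0495 with an estimated correlation). The p53 targets had 19 of 33 higher and 1 lower (adjusted over the list alone, 20 and 1; median 0.38, adjusted p = 0.000315, and adjusted p = 0.0657 with an estimated correlation). Formative and primed genes had 10 of 20 lower and 2 higher (adjusted over the list alone, 11 and 2; median -0.32, adjusted p = 0.000473, and adjusted p = 0.256 with an estimated correlation). Fibroblast and feeder markers had 6 of 13 lower and 1 higher, the same numbers adjusted over the list alone (median -0.70, adjusted p = 0.0361, and adjusted p = 0.256 with an estimated correlation). That call was lost without Control DMSO replicate 1 (0.157), Control GANC replicate 2 (0.0739) or HSVTK GANC replicate 1 (0.0745).

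**Figure D3:**
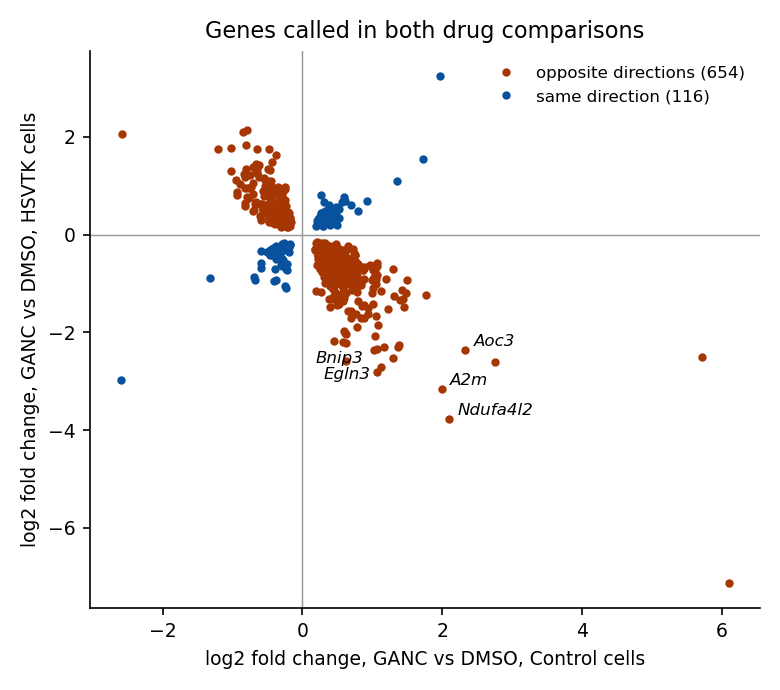
Log2 fold changes of the 770 genes called in both drug comparisons, with Control cells on the horizontal and HSVTK cells on the vertical axis and 1 point per gene. In red, 654 genes lie in opposite directions, among them Egln3 at 1.13 and -2.70, and the 2 points beyond 5 on the horizontal axis, Fhad1 and Stc1, have no counts in Control DMSO, so that their fitted values are not bounds.

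Without the drug, HSVTK and Control cells already differed widely, and the largest drops among named genes were in 4 imprinted genes, which are expressed from 1 parental copy. Meg3, a non-coding RNA of the Dlk1-Dio3 locus expressed from the maternal copy, stood at 180 ± 9.74 CPM (SD, n = 2) in Control DMSO and 0.414 ± 0.296 CPM in HSVTK DMSO, a log2 fold change of -8.78 ± 0.16 (adjusted p = 8.92e-26). Its neighbours Rian and Mirg fell by 7.67 ± 0.12 and 9.17 ± 0.38 on the log2 scale. Mirg had 2 counts over both HSVTK DMSO libraries, which makes Control DMSO 639 times higher with a counting interval of 176.5 to 5283. That interval is wider than the standard error of Mirg implies. Standard errors of genes this scarce in HSVTK cells, Meg3 among them, are too small. Rtl1, a retrotransposon-derived gene of the locus whose reads cannot be told from antisense ones, had 0 counts in HSVTK DMSO and 308 in Control DMSO and was at least 108-fold lower, with the floor at 3 counts over the group. Grb10, an imprinted growth inhibitor, went the other way, from 48.2 ± 0.704 to 457 ± 10.7 CPM (log2 fold change 3.24 ± 0.06). Of 32 imprinted genes, 14 were lower and 2 higher (adjusted over the list alone, 15 and 2; median -0.26, unmoved with Rtl1 at its bound, adjusted p = 0.000548, and adjusted p = 0.11 with an estimated correlation). Intervals and floors cover counting error only.

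**Figure D4:**
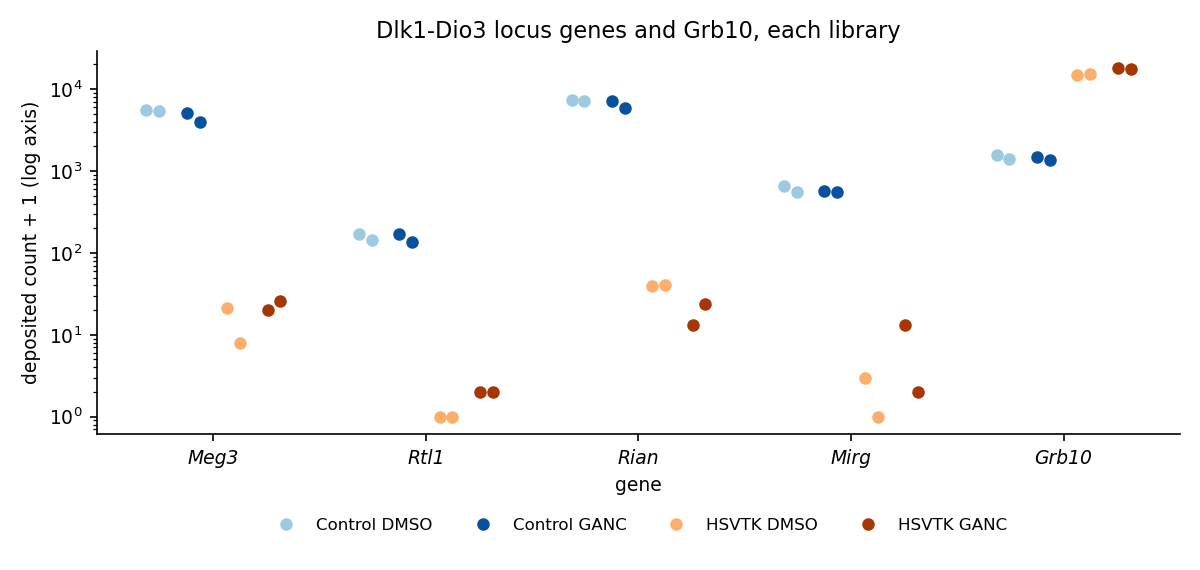
Deposited counts plus 1 per library on a log axis for 4 genes of the Dlk1-Dio3 locus and for Grb10, with 1 point per library. Rtl1 has 0 counts in both HSVTK DMSO libraries, and Grb10 has 14916 and 15394 counts there against 1583 and 1396 in Control DMSO.

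Other lists also separated HSVTK from Control cells under DMSO, as labelled. Relative to Control DMSO, the mean log2 level was 0.64 in HSVTK DMSO and -0.18 in HSVTK GANC for glycolysis and hypoxia, 0.48 and -0.06 for cholesterol synthesis and -0.38 and -0.06 for p53 targets, so these differences depend on which HSVTK libraries are compared. Glycolysis and hypoxia had 24 of 31 genes higher and 3 lower, the same numbers adjusted over the list alone (median 0.61, adjusted p = 2.35e-08, and adjusted p = 0.11 with an estimated correlation), with Bnip3 at 2.15 ± 0.09 and Egln3 at 1.84 ± 0.10. Cholesterol synthesis had 19 of 24 higher and 0 lower (adjusted over the list alone, 20 and 0; median 0.49, adjusted p = 2.35e-08, and adjusted p = 0.103 with an estimated correlation), with Dhcr7 at 1.15 ± 0.08. The p53 targets had 21 of 33 lower and 4 higher, the same numbers adjusted over the list alone (median -0.40, adjusted p = 0.000113, and adjusted p = 0.103 with an estimated correlation), with Plk2 at -1.06 ± 0.09 and Ccng1 at -0.90 ± 0.06. Trp53 (-0.32 ± 0.06, adjusted p = 0.000203), Cdkn1a (-0.68 ± 0.09, adjusted p = 1.07e-06) and Mdm2 (-0.33 ± 0.07, adjusted p = 0.000177) were lower too. Germline genes had 11 of 26 higher and 0 lower, also adjusted over the list alone (median 0.30, adjusted p = 0.0106, and adjusted p = 0.314 with an estimated correlation), with Stra8 at 2.93 ± 0.12 and Mael at 1.05 ± 0.10. Telomere maintenance had 9 of 20 lower and 2 higher (adjusted over the list alone, 10 and 3; median -0.19, adjusted p = 0.0358, and adjusted p = 0.273 with an estimated correlation), among them Atrx at -0.63 ± 0.07. Its call was lost without Control DMSO replicate 1 (0.0622), Control DMSO replicate 2 (0.0611), HSVTK DMSO replicate 1 (0.134), HSVTK GANC replicate 1 (0.0544) or HSVTK GANC replicate 2 (0.0544). The 2C list had 2 of 28 genes higher and 1 lower (adjusted over the list alone, 2 and 0; median -0.02, mean 0.07, adjusted p = 0.929). Its member Zscan4d was higher by 0.66 ± 0.17 (adjusted p = 0.00363, and 0.0734 without Control DMSO replicate 2 and 0.069 without HSVTK DMSO replicate 2), and Zscan4c (-0.18), Zscan4f (0.01) and Zfp352 (-0.75) did not pass. Naive pluripotency had 12 of 29 higher and 7 lower (adjusted over the list alone, 13 and 8; adjusted p = 0.245, and 0.0032 in the fry test), led by Tbx3 at 1.92 ± 0.07. Primitive endoderm had 7 of 20 higher and 2 lower (adjusted over the list alone, 8 and 2; adjusted p = 0.0637, and 0.0454 without HSVTK DMSO replicate 2), with Gata6 at 3.40 ± 0.50 from 0.176 ± 0.0556 to 1.91 ± 0.147 CPM.

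Besides these and Stra8, the largest differences among named genes under DMSO were in A2m at 4.16 ± 0.19, Tbx3os2 at 3.42, Ndufa4l2 at 3.39 ± 0.18, Nxph4 at 3.08, Aoc3 at 3.06 and the tuft cell factor Pou2f3 at 2.93, and in Serpina3m at -4.30 ± 0.49, Mir142hg at -3.54, the metalloprotease Adamts1 at -3.32 and Nkx2-9 at -3.02. Tk1 was higher by 0.41 ± 0.07 (adjusted p = 5.17e-05). Nanog was higher by 0.18 ± 0.05 (adjusted p = 0.00926), a call lost without Control DMSO replicate 1 (0.132), HSVTK DMSO replicate 1 (0.0848) or HSVTK DMSO replicate 2 (0.0708). Pou5f1 (0.08) and Sox2 (0.04) did not pass. In all, edgeR called 6060 genes, 2957 higher and 3103 lower in HSVTK cells, and 1390 changed at least 2-fold. With library size scaling 3233 were higher and 2818 lower. The count was 1080 in a test against a 1.5-fold change and 3652 with limma on unfiltered log2(FPKM + 1).

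With the drug, the 2C list separated both cell groups: 20 of 28 genes were higher and 0 lower in HSVTK GANC than in Control GANC (adjusted over the list alone, 24 and 0; median 1.27, adjusted p = 5.66e-11, and adjusted p = 0.0512 with an estimated correlation). Relative to Control DMSO, the mean log2 level of the list was -0.20 in Control GANC, 0.99 in HSVTK GANC and 0.06 in HSVTK DMSO, and that of glycolysis and hypoxia 0.36, -0.18 and 0.64, so both differences rest on the treatment labels of the HSVTK libraries. Zscan4c was higher by 0.93 ± 0.18, Zscan4d by 1.26 ± 0.17 and Zscan4f by 1.21 ± 0.21. Glycolysis and hypoxia had 24 of 31 lower and 0 higher (adjusted over the list alone, 25 and 0; median -0.44, adjusted p = 5.66e-11, and adjusted p = 0.131 with an estimated correlation), with Egln3 at -1.99 ± 0.10 and Slc2a1 at -1.07 ± 0.05. Cholesterol synthesis had 15 of 24 lower and 1 higher, the same numbers adjusted over the list alone (median -0.26, adjusted p = 0.00163, and adjusted p = 0.183 with an estimated correlation), with Insig1 at -0.52 ± 0.07. Formative and primed genes had 13 of 20 lower and 3 higher, the same numbers adjusted over the list alone (median -0.50, adjusted p = 0.000256, and adjusted p = 0.183 with an estimated correlation), with Lef1 at -1.46 ± 0.12 and Dnmt3b at -0.72 ± 0.06. Of 32 G2/M genes, 14 were lower and 1 higher, the same numbers adjusted over the list alone (median -0.14, adjusted p = 0.00379, and adjusted p = 0.183 with an estimated correlation), led by Pttg1 at -1.09 ± 0.08. Of these, 3 lie in the segments described below, Mad2l1 (-1.08) on chromosome 6 and Bub1b (-0.59) and Nusap1 (-0.68) on chromosome 2. Primitive endoderm had 8 of 20 higher and 2 lower (adjusted over the list alone, 10 and 2; median 0.55, adjusted p = 0.00874, and adjusted p = 0.183 with an estimated correlation), with Gata6 at 3.96 ± 0.56 and the collagen Col4a1 at 1.13 ± 0.14. The p53 targets had 8 of 33 higher and 7 lower (adjusted over the list alone, 8 and 9; median -0.02, adjusted p = 0.858, and 0.0213 in the fry test).

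Imprinted genes again had 13 of 32 members lower and 5 higher under GANC (adjusted over the list alone, 15 and 6; median -0.27, adjusted p = 0.00677, and adjusted p = 0.183 with an estimated correlation). Rian fell by 8.54 ± 0.13 and Meg3 by 7.71 ± 0.15 on the log2 scale relative to Control GANC, and Mirg by 6.43 ± 0.29. As under DMSO, these standard errors understate the error where HSVTK counts are few. Rtl1 had 2 counts over both HSVTK GANC libraries, which makes Control GANC 149 times higher with a counting interval of 40.8 to 1233. Grb10 was higher by 3.63 ± 0.06, followed among named genes by Hopx at 2.44, the glutathione peroxidase Gpx2 at 2.36, the citrate transporter Slc13a5 at 2.27, Zan at 2.26, Lonrf2 at 2.22, the cyclooxygenase Ptgs1 at 2.21 and Tmprss11d at 2.15. Xlr3b at -2.82, Dlk1 at -2.74 ± 0.40, Smoc1 at -2.73 and Rhox9 at -2.64 were lower. Sox2 stood at -0.46 ± 0.05 and Cdkn1a at -0.43 ± 0.09 (adjusted p = 0.000602), Nanog was higher by 0.22 ± 0.05 (adjusted p = 0.00253), and Tk1 stood at 0.24 ± 0.07 (adjusted p = 0.0132, and 0.199 without Control GANC replicate 1, 0.0514 without HSVTK GANC replicate 1 and 0.063 without HSVTK GANC replicate 2). Zfp352 (1.54), Pou5f1 (0.06), Mdm2 (0.07) and Trp53 (-0.15) did not pass, except Zfp352 without Control GANC replicate 1 (0.0209) and Trp53 without Control GANC replicate 1 (0.0157), without HSVTK GANC replicate 1 (0.00811) and with no filter on low counts (0.026). In all, edgeR called 4685 genes, 2004 higher and 2681 lower, so that 42.8% were higher, and 1022 changed at least 2-fold. With library size scaling 2579 were higher and 2190 lower (54.1% higher), so the balance of both directions rests on the scaling. The count was 2982 without HSVTK GANC replicate 2, 589 in a test against a 1.5-fold change and 2288 with limma on unfiltered log2(FPKM + 1). Calls in both comparisons of HSVTK with Control cells numbered 2352, of which 616 were higher in both, 1012 lower in both and 724 opposite. Independent lists would share 329.7 higher and 463 lower, and these comparisons share no library.

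The series concerns genomic stability, so genes were also grouped by chromosome. Among the autosomes and X, limma's camera test over all tested genes passed for chromosome 6 in HSVTK GANC against Control GANC (adjusted p = 0.00155, and adjusted p = 0.0271 with an estimated correlation). The median was -0.16 over its 605 genes with a mean CPM of at least 1. Under DMSO chromosome 6 had a median of -0.13 (adjusted p = 0.0662, and adjusted p = 0.0795 with an estimated correlation), and of -0.07 over genes with a mean CPM of 10 or more (adjusted p = 0.0296). Chromosome 2 had a median of -0.09 under DMSO (adjusted p = 0.204, 0.0208 with an estimated correlation, and 0.0296 over genes with a mean CPM of 10 or more). Under GANC its median was -0.07 (adjusted p = 0.361, 0.0271 with an estimated correlation, and 0.218 over genes with a mean CPM of 10 or more). No chromosome passed in the drug comparisons (lowest adjusted p = 0.299 in Control cells, for X, which became 0.0277 over genes with a mean CPM of 10 or more).

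Both shifts came from single segments of these chromosomes. A running median over 31 neighbouring expressed genes, made after the chromosome result was seen, found in the DMSO libraries a stretch of chromosome 6 from Scrn1 to Tmf1 and a stretch of chromosome 2 from Dnajc10 to Sord. In the chromosome 6 segment the 130 genes had a median log2 fold change of -0.97 (quartiles -1.18 and -0.76), which is 0.509 of the Control level, and 123 were called lower in HSVTK DMSO. In the GANC libraries, which did not set its ends but whose chromosome 6 result had prompted the search, the median was -0.96, all 130 genes lay below 0 and 126 were called lower. In the chromosome 2 segment the 174 genes had medians of -0.57 under DMSO (135 called lower) and -0.53 under GANC (147 called lower), or 0.675 and 0.69 of the Control level. The rest of each chromosome had medians between -0.03 and 0.08. Between GANC and DMSO, within either cell group, the segment medians lay within 0.0186 of 0. Each HSVTK library had the shift, with chromosome 6 medians from -0.953 to -0.983 and chromosome 2 medians from -0.54 to -0.576 relative to Control DMSO. Genes in these segments include the end joining factor Trp53bp1 at -1.36 ± 0.07, the helicase subunit Mcm2 at -0.81 ± 0.06, the spindle checkpoint gene Mad2l1 at -1.09 ± 0.06 and the demethylase Tet3 at -1.07 ± 0.16, all under DMSO. Trp53bp1 fell farther than most of the chromosome 2 segment, whose quartiles under DMSO were -0.82 and -0.31. Without the 512 tested genes between the ends of both segments, the counts were 5725 in place of 6060 and 4362 in place of 4685. Under DMSO 2947 of these were higher and 2778 lower, so the excess of lower calls there rests on the segments.

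**Figure D5:**
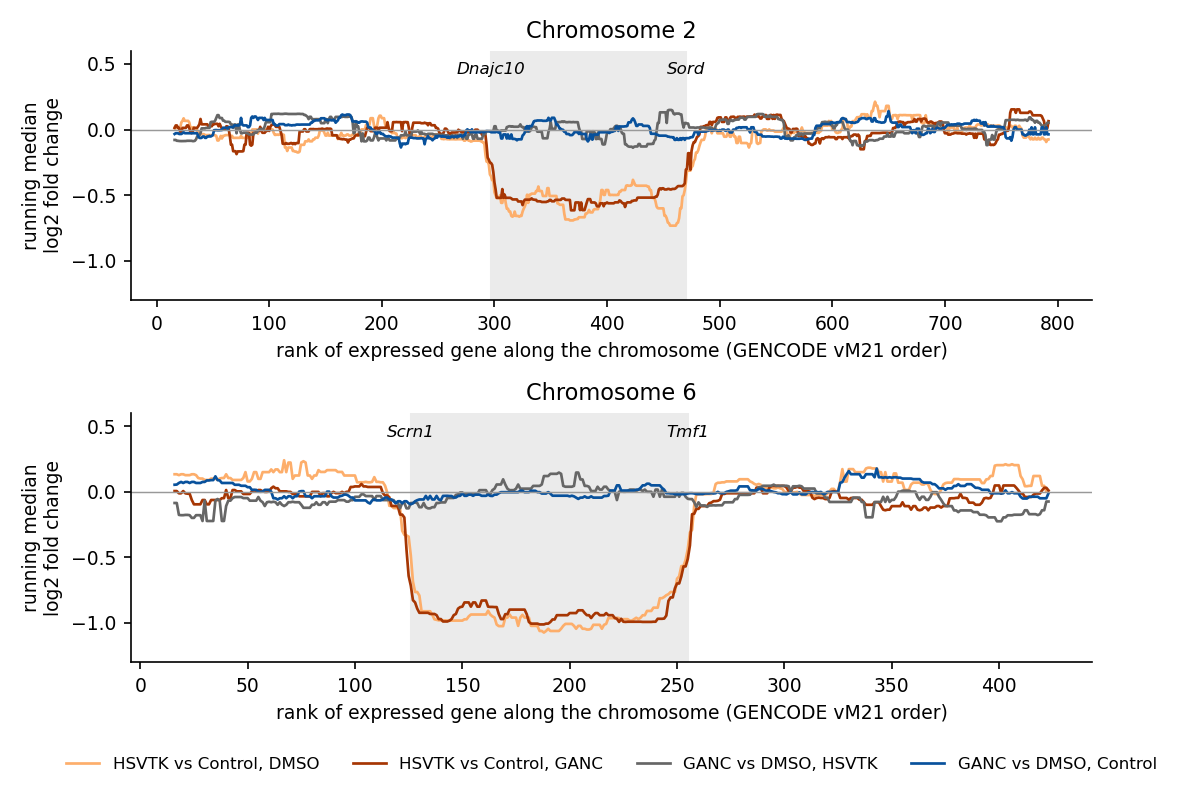
Running median log2 fold change over 31 expressed genes against gene rank along chromosomes 2 and 6, with 1 line per comparison and the called segments shaded. HSVTK against Control lies near -0.97 in the chromosome 6 segment and near -0.57 in the chromosome 2 segment, and both drug comparisons stay near 0.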

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

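The tests of explanations in this part were chosen after the results were seen, while the tests of the difference of response were fixed before. What brought each value here is a difference between Control and HSVTK cells in their response to GANC, tested as an interaction, which 4595 genes passed.

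The 2C-state genes were higher in the libraries labelled HSVTK GANC, with a median difference of response of 1.31 (Zscan4c 1.10, Zscan4f 1.20). Counts moving between near-identical copies are argued against, because the summed Zscan4 family rose by 1.00 on the log2 scale, from 35.3 to 70.6 CPM, with no overlap of the libraries. Exchanged treatment labels within the HSVTK cells and a culture state that differed at harvest may each lie behind the pattern. Both ask for the same values, so they cannot be told apart. These are the 84.9% of shared calls that move in opposite directions and the median response difference of -0.83 for glycolysis and hypoxia genes. An exchange within the Control cells alone would leave the 2C-state genes higher in the libraries labelled HSVTK GANC. Relative to Control DMSO, their mean log2 level was 0.06 in HSVTK DMSO and -0.20 in Control GANC. With HSVTK labels exchanged, the treated HSVTK cells would thus lie no lower than the Control groups. This does not decide, as both cell groups may differ without the drug. A response of the HSVTK cells to the drug itself stays open and was not tested.

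Other lists with a different response had median differences of -0.32 (formative and primed), -0.70 (fibroblast and feeder markers), 0.38 (p53 targets) and -0.73 (cholesterol synthesis). With an estimated correlation the first 3 lost their call (adjusted p = 0.256, 0.256 and 0.0657), and fibroblast and feeder markers also lost it without Control DMSO replicate 1 (0.157), Control GANC replicate 2 (0.0739) or HSVTK GANC replicate 1 (0.0745). Higher responses in HSVTK cells were those of Tbx20 (3.12), Cemip (2.97), Ms4a10 (2.95), Mc5r (2.94), Nkx2-9 (2.93), Itga8 (2.82), Pkd1l2 (2.79), Vmn2r79 (2.77) and Mdm2 (0.40). Lower responses were those of Ndufa4l2 (-5.88), A2m (-5.15), Aoc3 (-4.69), Aurkc (-3.88), Egln3 (-3.83), Grin1 (-3.82), Loxl2 (-3.65), Copz2 (-3.61) and Sox2 (-0.50).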

How the results depend on the processing

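No count, list test or named gene turned its direction past the threshold under any setting, but the balance of higher and lower calls depends on the setting. With library size scaling it turned from 2391 higher and 2728 lower to 2758 and 2325 for GANC in HSVTK cells, from 2957 and 3103 to 3233 and 2818 for HSVTK against Control under DMSO, and from 2004 and 2681 to 2579 and 2190 under GANC. With limma on log2(FPKM + 1) it turned for the same comparisons (2043 and 1662, 2484 and 2187, 1910 and 1531) and for the difference of responses, from 2087 and 2508 to 1684 and 1649. Without the genes of both segments it turned under DMSO, to 2947 and 2778. In the order GANC in HSVTK cells, GANC in Control cells, difference of responses, HSVTK against Control under DMSO and under GANC, the counts of called genes were 486, 6, 815, 1080 and 589 in a test against a 1.5-fold change, which asks for more by construction, and 2615, 29, 1981, 3652 and 2288 with limma on unfiltered log2(FPKM + 1). For GANC in Control cells they were 562 with limma on log2(FPKM + 1), 519 with a pseudocount of 0.1 and 923 with only the 4 libraries compared, a fit with fewer samples. The cause of the other changes was not tested. All other planned settings left the counts within 1.5 times (DESeq2: 4189, 1386, 3787, 5115 and 3828). Leaving out each library gave 3295 to 5637, 431 to 1949, 3460 to 4608, 4358 to 6571 and 2982 to 4535, where the lone library of its group is assumed to vary like the other groups. The 2C list kept its side of the threshold in each of these fits, with adjusted p from 2.9e-09 to 2.8e-07 for GANC in HSVTK cells, 0.113 to 0.403 in Control cells and 1.1e-07 to 3.2e-06 for the difference.

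Over all list tests, 1092 leave-one-out results kept their side, 15 lost the call and 13 gained it. With an estimated correlation 24 lost the call. Gains numbered 4 with library size scaling, 38 in the fry test and 102 in its version for mixed directions, which do not compare members with other genes. For named genes 303 leave-one-out results lost a call and 16 gained it, against 4545 that kept their side, and in the other settings 699 lost it and 4 gained it, against 5688. Calls lost at least once, leaving aside the 1.5-fold test and the unfiltered fit, were 21 of 125, 64 of 88, 13 of 124, 10 of 121 and 14 of 120 in the order above. Without the genes of both segments, a setting added after seeing the data, the counts were 4979, 1417, 4454, 5725 and 4362. As a replicate block, the shared replicate number gave 4932, 1339, 4433, 5882 and 4517 and left 138 list results on their side, while primitive endoderm (0.0481) and replication-dependent histones (0.0474) gained a call under DMSO. Same-numbered libraries did not deviate together (correlations from -0.0636 to 0.0243), so no pairing by number was seen. The labels do not say what the numbers mean, and a weak pairing cannot be excluded. Depth limits Duxf3 and Zfp352, with 0 to 4 and 2 to 26 counts per library.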

Other observations

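The tests of explanations in this part were chosen after the results were seen. Few genes of the repair lists lie in the segments of chromosomes 2 and 6 that were lower in HSVTK cells: 1 of 19 for end joining, 2 of 35 for mismatch and excision repair and 1 of 25 for nucleoside metabolism. No enrichment was tested, and the genes named here were picked after their values were seen. Trp53bp1, which steers breaks toward end joining, stood at -1.36 under DMSO and -1.29 under GANC, Xpc, the damage sensor of nucleotide excision repair, at -0.97 and -0.99, and Dguok, the mitochondrial deoxyguanosine kinase, at -1.50 and -1.20, all called. Ddb2, another damage sensor, stood at -0.23 (adjusted p = 0.263) and -0.17 (adjusted p = 0.461). Under DMSO, Trp53bp1 and Dguok lay beyond the lower quartile of their segments (-0.82 on chromosome 2 and -1.18 on chromosome 6).

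Interferon response genes went both ways. In HSVTK against Control cells under DMSO, the RNA sensor Rigi fell by 0.90 ± 0.07 on the log2 scale, Irf9 by 0.94 ± 0.15 and Ifitm3 by 1.65 ± 0.07, while the class I antigens H2-K1 and H2-D1 rose by 1.08 ± 0.10 and 1.21 ± 0.12. Under GANC, Rigi stood at 0.29, Irf9 at 0.64, Ifitm3 at -0.91 and H2-D1 at 0.46, all called, and H2-K1 at -0.10 (adjusted p = 0.518). B2m, on the same list and in the chromosome 2 segment, was called lower in both, at -0.95 under DMSO and -0.45 under GANC. Among mitochondrial genes, mt-Cytb was lower by 0.60 in HSVTK DMSO than in Control DMSO and higher by 0.44 in HSVTK GANC than in HSVTK DMSO. Both values use the same HSVTK DMSO libraries, so they are not independent. Between HSVTK GANC and HSVTK DMSO the mitochondrially encoded list had 6 of 13 members higher and 1 lower and did not pass the camera test (adjusted p = 0.138).

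The segments of chromosomes 2 and 6 were lower in every HSVTK library. Chance clustering is argued against, because the farthest running median in 1000 shuffled gene orders was 0.506, against -0.73 in the chromosome 2 and -1.07 in the chromosome 6 segment. GANC in Control cells also went beyond its shuffles (-0.30 against 0.233), where no segment was called. A response to the drug is argued against, because the segment medians in the drug comparisons lay no farther from 0 than -0.0186. The same holds for a culture state that differed between treatments. A culture state shared by all libraries of a cell group would cancel in these comparisons, so they cannot decide on it. A copy number difference between the cell groups is consistent with medians of -0.96 for chromosome 6 and -0.53 for chromosome 2 in the GANC libraries. It remains a hypothesis: those libraries did not set the ends of the segments, but their chromosome tests had been seen, no DNA was measured here and regulation of a whole segment was not tested.

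Meg3, Rian, Mirg and Rtl1 were nearly absent from the HSVTK libraries. Loss of a stretch of chromosome 12 that reaches the neighbours of the locus is argued against by the median of 0.033 over 20 expressed neighbours under DMSO (quartiles -0.15 and 0.19, 4 called lower and 5 higher). Under GANC their median was -0.16 (quartiles -0.24 and 0.00, 8 called lower and 1 higher), also far from the loss of a copy. A switch of the maternal copy to the paternal pattern asks for a level or higher Dlk1, which is expressed from the paternal copy. Dlk1 instead fell by 1.81 ± 0.37 on the log2 scale under DMSO and was also lower under GANC, which goes against a switch. It is 1 gene, however, and cannot decide this alone. Such a switch therefore stays open. A smaller deletion inside the locus and silencing of both copies also stay open and were not tested.

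A hypothesis was that the level of p53 targets sets that of the 2C-state genes, which might make both rise together. p53 targets were higher by a median of 0.32 in HSVTK GANC than in HSVTK DMSO, so a similar rise over Control GANC would be needed, where the 2C-state genes were higher too. There the upper quartile of the p53 targets was 0.24, below that median, and their median was -0.02. The hypothesis does not account for the difference of the 2C-state genes between the cell groups under GANC.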
